A study of Homo sapiens with 39 samples.

How the data were processed

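RNA of 39 samples was labelled by the 3' IVT Express method and hybridised to Affymetrix arrays with 54675 probe sets, per the labels' protocols. The deposited table holds 1 column of log2 values per array, and the submitters' processing notes name RMA, which corrects the background, makes the arrays' distributions alike and summarises the probes of a set, and Partek 6.5. Options and the order of steps are not given in the sources used here. That the scale is log2 was taken from the values, which run from 1.95 to 15.1. RMA makes values relative to the whole array, so a shift of all transcripts in 1 direction would be hidden. The arrays were not normalised again, 0 pairs of arrays held identical values, and all value columns belonged to the 39 samples.

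Groups were taken from the labels: unexposed cells at 0, 6, 24 and 72 h, and cells exposed to 0.1 or 10 µM VX at 6, 24 and 72 h. Gene names came from the array's annotation table and were checked by gene number against a current gene table, which matched 41037 probe sets and changed 0 symbols. Of the probe sets, 41091 had 1 symbol, 1801 had several and were not named, and 11721 had none there, after 62 control probe sets were set aside. Probe sets above the 40th percentile of all values (4.71) on at least 3 arrays were tested, 35877 in all, covering 14851 genes. The filter acts on brightness, and dim probe sets understate differences.

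One mean per group was fitted to all arrays with limma 3.58.1 in R 4.3.3 (29 residual degrees of freedom, 3.85 prior), and each contrast was tested with its moderated test and Benjamini-Hochberg adjustment, with a threshold of 0.05. The 6 comparisons of VX with unexposed cells of the same time, 3 of the concentrations and 3 of times in unexposed cells were made, and 2 moderated F tests asked whether the VX effect differed between times. The p-values measure the spread between arrays of a group. The 27 gene lists and 12 cell type marker lists, written down before the data were examined, were tested with camera at a preset correlation of 0.01, with 1 probe set per gene, the one with the highest mean, and adjustment over the 39 lists of a comparison. None of the marker lists except that of neurons, in unexposed cells at 72 h, passed in camera in any comparison. No camera call held at an estimated correlation. Of these calls, those of the cell cycle, p53 and ATF4 lists at 6 h without VX and of the p53, apoptosis, cholesterol synthesis, oxidative phosphorylation and axon guidance lists at 72 h without VX also passed in fry, which tests whether the genes of a list move 1 way on balance.

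A gene was represented by its probe set with the highest mean over the 39 arrays, among those with 1 symbol, and named genes are those that passed and whose arrays did not overlap between groups, by size of the difference, 10 in each direction for VX and 8 for unexposed cells, and up to 4 members of each list described, taken by unadjusted p, with ACHE and BCHE in each VX comparison. Fewer than 10 met the rule for rises at 72 h after 0.1 µM. The 3' minus 5' values of control probe sets were compared with 2-sided exact permutation tests of the means, and within pairs with exact tests over all sign changes, chosen after the data were seen.

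The labels number the replicates alike in all groups. The numbers were taken to pair the samples where every pair of same-numbered arrays had deviations from the group means correlated above 0.1: 10 µM against unexposed cells at 6 h (lowest 0.115), 0.1 µM against unexposed cells at 6 h (0.317) and 24 h (0.210), and 10 µM against 0.1 µM at 6 h (0.321).

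The alternatives fixed before the data were examined were other filters, only the arrays of the compared groups, the replicate number as a block, a robust trended prior, no shrinkage, array weights, centred arrays, other probe sets of a gene and leaving out each array. The ACTB and GAPDH 3' minus 5' values as covariates and leaving out all arrays numbered 1 were added after the data were seen.

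The procedure was tested on data simulated for 10 µM against unexposed cells at 24 h, with 200 of 35877 probe sets changed. It recovered 52% of log2 changes of 0.5 and 93% of those of 1 with 5 false calls. With the ACTB covariate these were 34%, 86% and 6. With a simulated 3' bias, 314 false calls were made without the covariate and 7 with it. This does not test a bias that ACTB misses. A cell cycle list lowered by 0.2 was recovered and 0 others called, which does not test correlated genes. Small changes can be missed.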

Results

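The series measured messenger RNA on Affymetrix 3' expression arrays in hN2 cells, which are human neural cells made from the embryonic stem cell line WA09. The cells were left unexposed or were exposed for 1 h to 0.1 or 10 µM VX, an organophosphorus nerve agent that blocks acetylcholinesterase and butyrylcholinesterase, then washed and harvested after 6, 24 or 72 h. Unexposed cells were also harvested at 0 h. The 39 arrays form 10 groups with 4 arrays each, except the unexposed 6 h group with 3, and the series' design text calls the arrays of a group biological repeats. The deposited log2 values had array medians of 5.311 to 5.402, and correlations between arrays of a group lay between 0.983 and 0.996. The number of arrays limits the precision, and the median residual SD of a probe set was 0.165 on the log2 scale. Differences are given below as log2 values ± SE, with n = 4 against 4 arrays, or 4 against 3 where the 6 h controls enter.

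Control probe sets of the actin gene ACTB read its transcript near the 3' and the 5' end, and the 3' value minus the 5' value grows when RNA is degraded or labelled incompletely. This value was 0.80 ± 0.22 (SD, n = 4) in unexposed cells at 0 h, 1.45 ± 0.62 (n = 3) at 6 h, 2.32 ± 0.35 (n = 4) at 24 h and 2.35 ± 0.60 (n = 4) at 72 h. After 0.1 µM VX it was 2.75 ± 0.16 at 6 h, 2.60 ± 0.21 at 24 h and 2.40 ± 0.52 at 72 h (SD, n = 4 each). After 10 µM it was 3.61 ± 0.50, 3.50 ± 0.56 and 3.04 ± 0.72 (SD, n = 4 each). The 10 µM arrays lay above the unexposed arrays of the same time without overlap at 6 h and 24 h, as did the 0.1 µM arrays at 6 h (2-sided exact permutation test of the means, p = 0.0286 in each, the smallest the 6 h and 24 h designs allow). Over the family of 24 such tests the adjusted p of these 3 was 0.0686 (exact permutation test). At 72 h the exact p was 0.2 for 10 µM and 0.914 for 0.1 µM, and at 24 h it was 0.229 for 0.1 µM. There, where the replicate numbers pair the samples, the ACTB and the GAPDH values were higher after VX in 4 of 4 pairs (exact permutation of signs, p = 0.125 for each, the smallest that 4 pairs allow). At 6 h the numbers pair the samples too. Both values were higher after each concentration in 3 of 3 pairs (exact permutation of signs, p = 0.25, the smallest 3 pairs allow). In the unexposed cells the ACTB value was higher at 24 h and 72 h than at 0 h by 1.52 and 1.56 (exact permutation p = 0.0286 for each). The GAPDH control probe sets gave 1.41 ± 0.54 (SD, n = 4) after 10 µM at 6 h against 0.620 ± 0.095 (n = 3) in unexposed cells (exact permutation p = 0.0571). Their value was higher, without overlap, after 10 µM at 24 h by 0.474 and after 0.1 µM at 6 h by 0.331 (exact permutation p = 0.0286 and adjusted p = 0.0686 for each). In unexposed cells it was 0.292 higher at 24 h than at 0 h (exact permutation p = 0.0286). The control probe set near the 5' end of 18S ribosomal RNA differed between 10 µM and unexposed cells by -1.64 at 6 h, -1.73 at 24 h and -1.42 at 72 h (exact permutation p = 0.0286, 0.0286 and 0.0571, outside the family of 24). In unexposed cells it differed from 0 h by -0.96 at 6 h, -0.66 at 24 h and -0.49 at 72 h (exact permutation p = 0.0286, 0.0286 and 0.114).

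**Figure D1:**
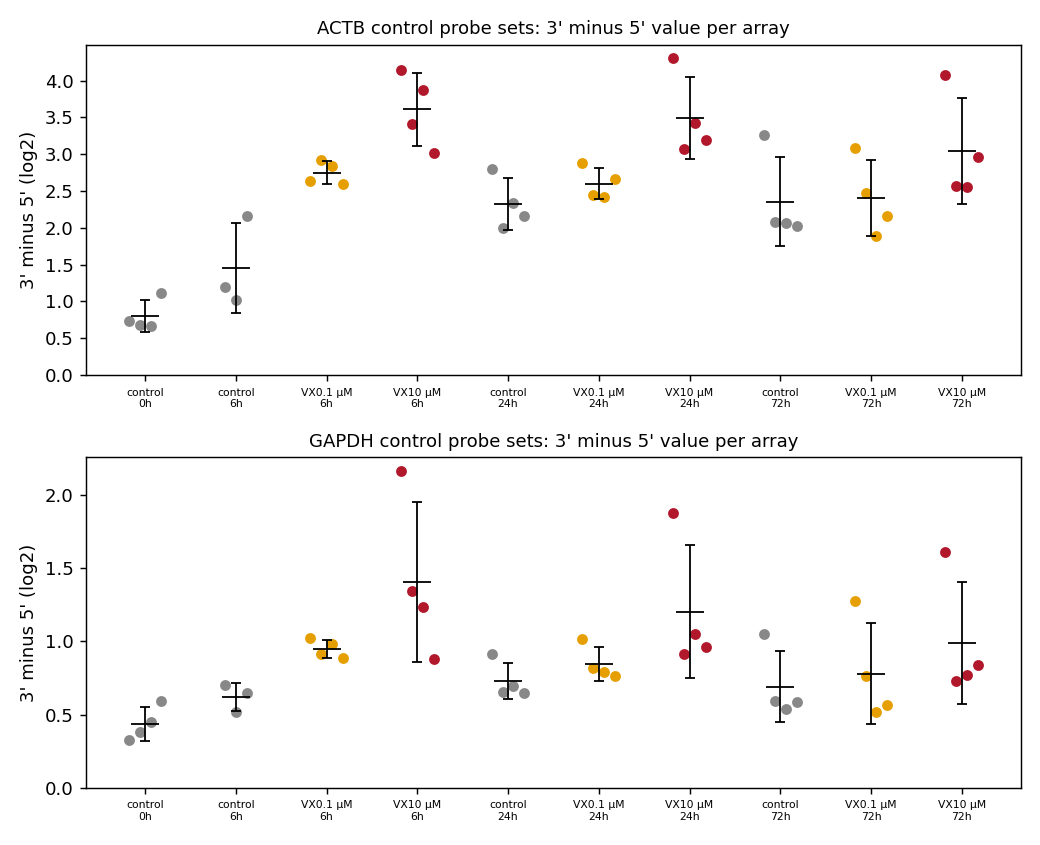
3' minus 5' value (log2) of the ACTB and GAPDH control probe sets per array, by group. Points are arrays, the horizontal mark is the group mean and the bars are ± 1 SD; the ACTB mean was 3.61 after 10 µM VX and 1.45 in unexposed cells at 6 h.

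The comparison of 10 µM VX with unexposed cells at 6 h asks which transcripts differ early after the exposure. THBS1, which encodes the secreted matrix protein thrombospondin 1, rose 1.84-fold (0.88 ± 0.18, adjusted p = 0.00189). ACSL4, a ligase of long-chain fatty acids, rose 1.63-fold (0.70 ± 0.14), and FLT1, a receptor of vascular endothelial growth factor, rose 1.64-fold (0.71 ± 0.15). SNORA21, IDNK, CAPN1, ROR1, RPL23AP32, LOC105371622 and XKR6 rose by 0.68 to 0.84. EIF5A, a translation factor, was 2.28-fold lower (-1.19 ± 0.29, adjusted p = 0.00767). CDC37, a partner of HSP90 in the folding of kinases, was 2.08-fold lower (-1.06 ± 0.17, adjusted p = 0.000379), and PSMC3, an ATPase of the proteasome, was 1.88-fold lower (-0.91 ± 0.17, adjusted p = 0.000896). BAGE2, PGD, PDAP1, PPIE, PPP5C, ANP32A and JUNB fell, with differences between -1.12 and -0.78. Probe sets elsewhere in THBS1, IDNK, XKR6, PGD and ANP32A included some with the opposite sign. Without control replicate 2 THBS1 was at 0.58 (adjusted p = 0.0385).

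Among gene groups at this time and concentration, 7 of 48 cell cycle genes fell, 0 rose and 41 did not pass (9 fell when adjusted over the list alone). Among them were AURKB, a kinase of mitosis, at -0.49 ± 0.11, TOP2A, the topoisomerase of dividing cells, at -0.46 ± 0.11, KIF2C at -0.37 ± 0.10 and MCM7 at -0.26 ± 0.07. The list as a whole was lower (median -0.12, camera adjusted p = 0.000184, and adjusted p = 0.954 with an estimated correlation). Of 33 immediate early genes, which respond to stimuli within minutes, 4 fell and 0 rose (5 and 1 when adjusted over the list alone). Those that fell were FOS (-2.73 ± 0.79, adjusted p = 0.0224), FOSB (-0.91 ± 0.28), JUNB (-0.78 ± 0.16) and IER2 (-0.58 ± 0.15). FOS, FOSB and JUNB had risen in the unexposed cells between 0 h and 6 h, as given below, so their falls are against risen controls. FOS arrays lay at 7.15 to 7.92 in unexposed cells at 0 h, 8.77 to 11.45 in those at 6 h and 5.96 to 9.14 after VX. Of 30 apoptosis genes 4 fell and 0 rose (4 and 0 when adjusted over the list alone). They were AIFM1, a mitochondrial flavoprotein, at -0.69 ± 0.16, BCL2L2, which opposes cell death, at -0.48 ± 0.12, CASP6, an effector caspase, at -0.39 ± 0.09 and BAX, which promotes death, at -0.35 ± 0.10. Of 35 genes of glycolysis and the hypoxia response 4 fell and 2 rose (5 and 2 when adjusted over the list alone). The glycolytic enzymes were ENO1 at -0.59 ± 0.14, PKM at -0.44 ± 0.12 and PGAM1 at -0.23 ± 0.07. The regulatory enzyme PFKFB3 was at 0.30 ± 0.09. These last 3 lists did not differ from other genes (camera adjusted p = 0.577, 0.359 and 0.985). For AURKB, TOP2A, CASP6 and PKM another probe set had the opposite sign. Those of CASP6 (0.34, adjusted p = 0.0255) and PKM (0.61, adjusted p = 0.0394) passed. FOS did not pass without control replicate 2 (-2.12, adjusted p = 0.148) or 3 (-2.62, adjusted p = 0.0546). Nor did it without VX replicate 1 (-2.54, adjusted p = 0.0685) or 4 (-2.22, adjusted p = 0.0595), and it was at -1.43 with the ACTB covariate (adjusted p = 0.560) and -2.00 with that of GAPDH (adjusted p = 0.209). In the fit with the replicate block, which pairs the samples here, FOS was at -2.43 (adjusted p = 0.000218). FOSB did not pass without control replicate 2 (-0.48, adjusted p = 0.342) or VX replicates 1 (-0.94, adjusted p = 0.0624), 3 (-0.84, adjusted p = 0.0837) or 4 (-0.85, adjusted p = 0.0522), or with the ACTB (-0.92, adjusted p = 0.272) or GAPDH covariate (-1.01, adjusted p = 0.0796). From the groups alone the adjusted p was 0.113 for FOS and 0.167 for FOSB. PGAM1 did not pass without control replicate 1 (-0.11, adjusted p = 0.326). The cell cycle list lost its call without VX replicate 3 (median -0.064, adjusted p = 0.189). For the enzymes VX inhibits, ACHE was at -0.022 ± 0.17 (adjusted p = 0.958) and BCHE at 0.15 ± 0.08 (adjusted p = 0.204, 0.23 with adjusted p = 0.0302 without VX replicate 4, and 0.29 with adjusted p = 0.000812 with array weights). Of the tested genes 0 of 10 of acetylcholine synthesis and breakdown and 0 of 12 acetylcholine receptors passed, both also when adjusted over the list alone. These VX arrays lay 2.16 above their controls in the ACTB 3' minus 5' value.

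In limma's moderated test 3874 probe sets of 2497 genes passed an adjusted p of 0.05, 1273 higher and 2601 lower (1659 and 2254 with each array centred on its median). With the replicate number as a block, which pairs the samples here, 6003 passed. With the ACTB value as a covariate 246 passed, 79 of them in both fits with 1 direction. ROR1 and XKR6 were the 2 of the 20 genes that did, and EIF5A, PSMC3, PPIE, AIFM1 and RPL23AP32 changed sign. The count was 1410 with the GAPDH value as covariate, 711 from the arrays of the 2 groups alone and 10693 with array weights. It was 1918 without control replicate 2, 2044 without control replicate 1, 2074 without VX replicate 1 and 2301 without VX replicate 2.

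**Figure D2:**
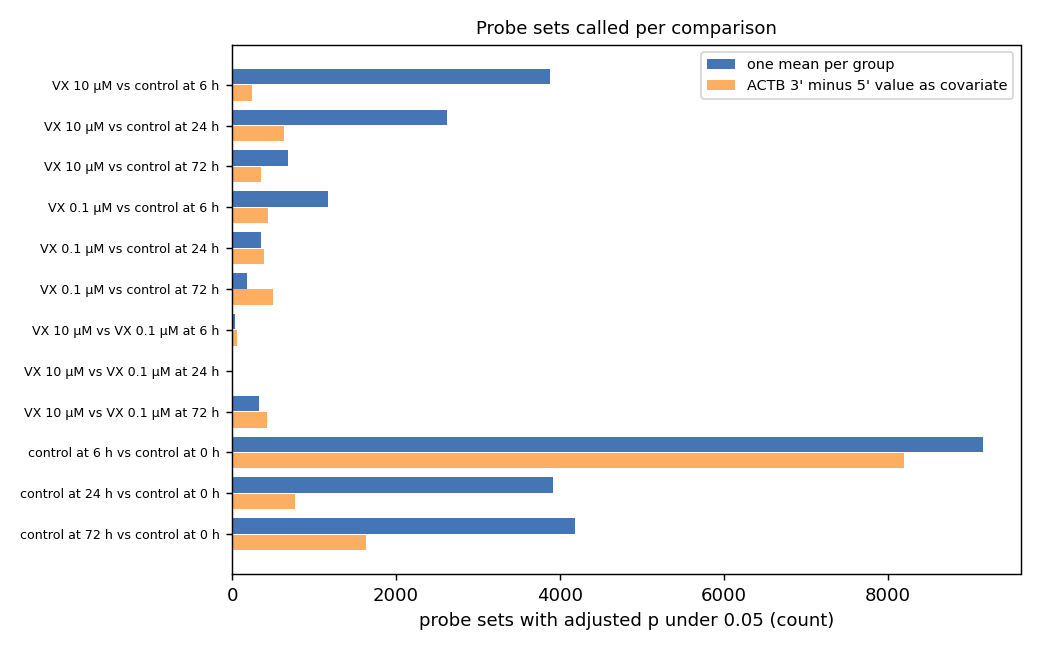
Number of probe sets with an adjusted p under 0.05 in each comparison (bars from 0), with 1 mean per group and with the ACTB 3' minus 5' value of each array as a covariate. At 6 h after 10 µM VX the count was 3874 without and 246 with the covariate.

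At 24 h after 10 µM VX, ZBTB20, a zinc finger repressor of transcription, rose 1.73-fold (0.79 ± 0.10, adjusted p = 0.000138), and 6 of its 10 other probe sets passed in the same direction. MICOS10P1 (0.94 ± 0.24), TBRG1 (0.83 ± 0.21), SDCBP2-AS1, CCDC142, RAB12, C3orf62, RPL32P3, MIGA1 and MIR181A2HG rose, the last 7 by 0.58 to 0.68. The linker histone genes H1-4 and H1-3, whose products bind DNA between nucleosomes, were 2.01-fold (-1.005 ± 0.30, adjusted p = 0.0360) and 1.86-fold lower (-0.90 ± 0.20, adjusted p = 0.00697). The probe set of H3-3A, which encodes histone H3.3, was 1.86-fold lower (-0.90 ± 0.20). KIF1A, a motor of axonal transport, was 1.93-fold lower (-0.95 ± 0.24). SYNC, MIF-AS1, CCDC18, BAGE2, PDAP1 and MED18 also fell, with differences between -1.24 and -0.82. BCHE, which encodes butyrylcholinesterase, rose 1.19-fold (0.25 ± 0.07, adjusted p = 0.0257), and ACHE was at -0.11 ± 0.16 (adjusted p = 0.718). TBRG1, SDCBP2-AS1, RAB12 and KIF1A each had another probe set of the opposite sign. Those of TBRG1 (-0.61) and RAB12 (-0.71) passed. BCHE did not pass without control replicate 2 (0.24, adjusted p = 0.0641) or 3 (0.24, adjusted p = 0.0688). It also did not pass without VX replicate 3 (0.22, adjusted p = 0.0967) or 4 (0.25, adjusted p = 0.0545), with centred arrays (0.23, adjusted p = 0.0577), the groups alone (adjusted p = 0.0731) or the GAPDH covariate (0.20, adjusted p = 0.0868).

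Of the 30 tested genes of the synapse and its vesicles 3 rose and 1 fell at 24 h after 10 µM, the same counts as when adjusted over the list alone. Those that rose were CPLX2 (0.50 ± 0.12) and CPLX1 (0.49 ± 0.13), which clamp vesicle fusion, and VAMP1 (0.45 ± 0.13), a vesicle fusion protein. HOMER2, a scaffold of the postsynaptic side, fell (-0.60 ± 0.15, camera adjusted p for the list 0.513). CPLX2 and VAMP1 each had another probe set of the opposite sign. Of 48 cell cycle genes 3 fell and 0 rose, also when adjusted over the list alone: TOP2A (-0.34 ± 0.10), MKI67 (-0.37 ± 0.11) and MCM2 (-0.27 ± 0.08). CDC45 was at -0.32 ± 0.12 (adjusted p = 0.0858). The list median was -0.082 (camera adjusted p = 0.000169, and adjusted p = 0.952 with an estimated correlation), and another probe set of MKI67 was at 0.19. Without control replicate 1 (median -0.032, adjusted p = 0.348) or VX replicate 3 (-0.045, adjusted p = 0.118) the list was not called. BCHE was the 1 gene of 10 in the list of acetylcholine synthesis and breakdown that passed, and 0 of 12 receptor genes and 0 of 18 neuron markers did (1, 0 and 2 when adjusted over the list alone). In the ACTB 3' minus 5' value the VX arrays lay 1.175 above the controls.

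Of the probe sets tested at 24 h, 2626 of 1801 genes passed, 1075 higher and 1551 lower (905 and 1896 with centred arrays). Given the ACTB covariate, 629 passed, 356 of them in both fits with 1 direction. Among these were 4 of the 20 genes, ZBTB20, C3orf62, MIGA1 and H3-3A, and BCHE was then at 0.15 ± 0.08 (adjusted p = 0.269). The count was 6377 with array weights, 1125 without VX replicate 3, 1290 without control replicate 3, 1566 without VX replicate 4 and 1686 without control replicate 1.

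At 72 h after 10 µM VX, ZNF345, a zinc finger gene, was 2.80-fold lower (-1.48 ± 0.17, adjusted p = 2.02e-06). AGO2, which encodes the slicing protein of small RNA silencing, was 1.75-fold lower (-0.81 ± 0.10, adjusted p = 1.31e-05). The histone genes H1-4 (-1.09 ± 0.30), H1-3 (-0.86 ± 0.20), H3-3A (-0.80 ± 0.20) and H2AC17 (-0.78 ± 0.11) fell. So did M6PR, a receptor that sorts lysosomal enzymes (-0.84 ± 0.19), TMEM192, ZNF830 and MIR302B, the last 3 between -0.74 and -0.69. Rises were smaller: IDNK by 0.69 ± 0.16, SLC8A2, a sodium and calcium exchanger of neurons, by 0.50 ± 0.13, and ZBTB20 by 0.41 ± 0.10. KLK2, NAT16, ARHGAP32, ZBTB44, CBX6, KAT6A and FOXP1 rose by 0.25 to 0.46. Among the probe sets of IDNK, ZBTB20, ARHGAP32, KAT6A, FOXP1 and ZNF830 some had the opposite sign. That of FOXP1 (-0.70, adjusted p = 0.00292) passed. Of 48 cell cycle genes 1 fell, TOP2A (-0.37 ± 0.10), also when adjusted over the list alone. PLK1 (-0.25 ± 0.11), MKI67 (-0.24 ± 0.11) and CENPE (-0.21 ± 0.09) did not pass. The list median was -0.072 (camera adjusted p = 0.00576, and adjusted p = 0.937 with an estimated correlation). The p53 and DNA damage list was lower (median -0.060, camera adjusted p = 0.00858, and adjusted p = 0.937 with an estimated correlation) although 0 of its 28 genes passed, also when adjusted over the list alone. BAX was at -0.31 ± 0.10, XPC, a DNA repair protein, at -0.27 ± 0.09, ZMAT3 at -0.22 ± 0.08 and PMAIP1 at -0.31 ± 0.14. MKI67 and ZMAT3 had further probe sets of the opposite sign. Without control replicate 1 the cell cycle list (median -0.053, adjusted p = 0.179) and the p53 list (-0.048, adjusted p = 0.179) were not called. Nor was the p53 list without VX replicate 3 (-0.042, adjusted p = 0.190), while without control replicate 3 its median was -0.094 (adjusted p = 0.00135). ACHE (-0.014 ± 0.16), BCHE (0.076 ± 0.07), the 10 genes of acetylcholine synthesis and breakdown and the 12 receptor genes did not pass. Here the ACTB 3' minus 5' value was 0.69 higher than in controls.

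At 72 h 677 probe sets of 503 genes passed, 93 higher and 584 lower. When the ACTB covariate entered the model 352 passed, 315 of them in both fits with 1 direction. Among these were 9 of the 20 genes, including ZNF345, AGO2, H2AC17, FOXP1 and KAT6A, while H1-4 was at -0.91 ± 0.31 and H1-3 at -0.65 ± 0.19 without passing. The count was 351 from the 2 groups alone, 2339 with array weights and 1283 without the arrays numbered 1. It was 290 without VX replicate 1, and 1087, 320, 339 and 369 without control replicates 1, 2, 3 and 4.

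**Figure D3:**
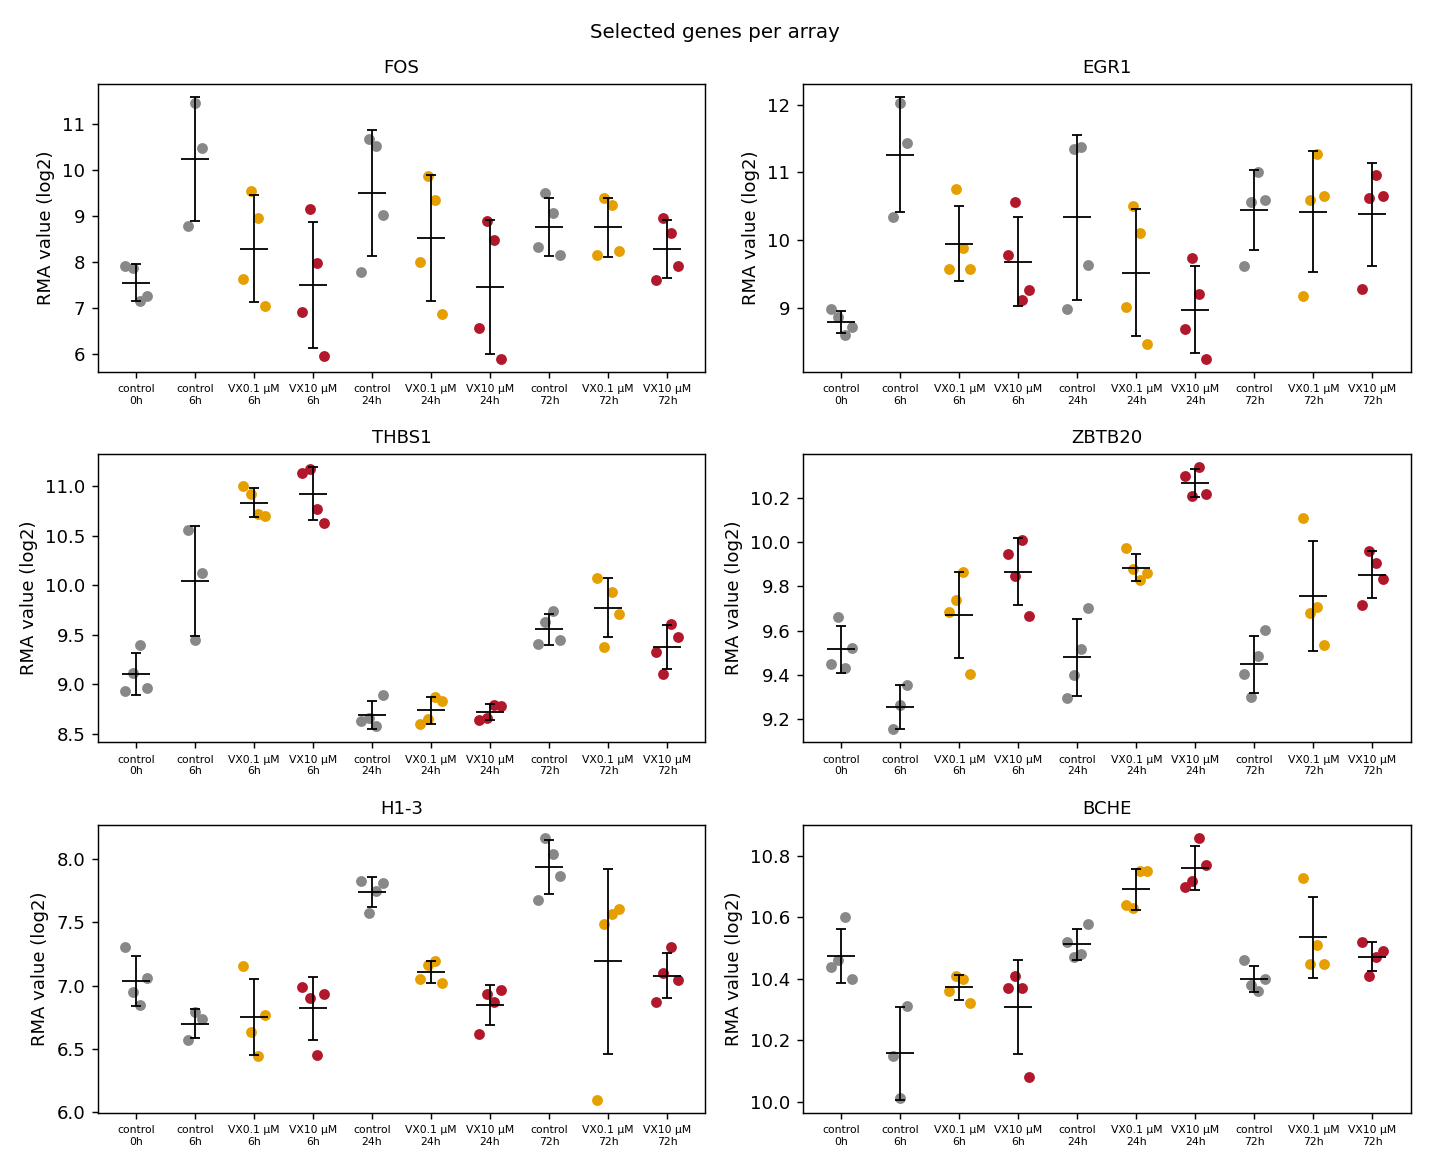
RMA value (log2) per array of 6 genes in the 10 groups, grey for unexposed cells, orange for 0.1 µM and red for 10 µM VX. Points are arrays, the horizontal mark is the mean and bars are ± 1 SD; ZBTB20 averaged 10.3 after 10 µM VX and 9.48 in unexposed cells at 24 h.

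After 0.1 µM VX at 6 h, THBS1 rose 1.73-fold (0.79 ± 0.18, adjusted p = 0.0147) and ELOVL4, an enzyme that lengthens very long fatty acids, rose 1.46-fold (0.55 ± 0.12, adjusted p = 0.0117). KRT16, ARHGAP30, BARX2, TUBB7P, TMEM45B, LINC03008, LINC02239 and REXO1 rose by 0.54 to 0.67. CNTN3, a neural adhesion protein of the contactin family, was 1.97-fold lower (-0.98 ± 0.16, adjusted p = 0.00262). TBC1D32, which is needed for cilia, was 1.92-fold lower (-0.94 ± 0.15), and CYP27B1, the enzyme that activates vitamin D, was 1.90-fold lower (-0.92 ± 0.25). BAGE2, INTS6L, RSRP1, ZNF767P, PI4KA, LINC01619 and ZNF692 fell too, with differences between -1.03 and -0.88. THBS1 and ARHGAP30 also had probe sets of the opposite sign. Without control replicate 2 THBS1 (0.49, adjusted p = 0.242), CYP27B1 (-0.59, adjusted p = 0.335) and ZNF767P (-0.60, adjusted p = 0.269) did not pass. Of 48 cell cycle genes 2 fell (6 when adjusted over the list alone), MCM2 (-0.31 ± 0.08) and MCM7 (-0.25 ± 0.07), subunits of the replicative helicase. AURKB (-0.37 ± 0.11, adjusted p = 0.0552) and CDC45 (-0.40 ± 0.13, adjusted p = 0.0660) passed with the replicate block, at adjusted p = 0.0391 and 0.0188. So did FOS, at -1.94 ± 0.79 without the block (adjusted p = 0.161) and -1.64 with it (adjusted p = 0.0160). The list median was -0.090 (camera adjusted p = 0.00454, and adjusted p = 0.886 with an estimated correlation). It was not called without control replicate 1 (-0.054, adjusted p = 0.194), VX replicate 3 (-0.050, adjusted p = 0.222) or VX replicate 4 (-0.079, adjusted p = 0.0667), and was at -0.14 without control replicate 3 (adjusted p = 8.42e-05). ACHE, with another probe set of the opposite sign, was at 0.062 ± 0.17 and BCHE at 0.22 ± 0.08 (adjusted p = 0.102, 0.29 with adjusted p = 0.0317 without control replicate 3, and 0.28 with adjusted p = 0.00826 with array weights). Again 0 of the 10 genes of acetylcholine synthesis and breakdown passed (1 higher and 1 lower when adjusted over the list alone). Their ACTB 3' minus 5' value was 1.29 higher than in the controls.

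In this comparison 1176 probe sets of 915 genes passed, 224 higher and 952 lower (397 and 417 with centred arrays). Of all tested, 2597 passed with the replicate block, which pairs the samples here. In the fit with the ACTB covariate 435 passed, 227 of them in both fits with 1 direction. Among these were 8 of the 20 genes, 7 that fell and ELOVL4. The count was 73 from the 2 groups alone, 4232 with array weights, and 1802 without the arrays numbered 1. It was 12 and 2003 without control replicates 2 and 3, and 642, 337 and 553 without VX replicates 1, 2 and 3.

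After 0.1 µM VX at 24 h, CCDC18 was 1.92-fold lower (-0.94 ± 0.19, adjusted p = 0.00844). HSP90B1, a chaperone of the endoplasmic reticulum, was 1.57-fold lower (-0.65 ± 0.12, adjusted p = 0.00375), and LDB1, a cofactor of LIM domain transcription factors, was 1.48-fold lower (-0.57 ± 0.09, adjusted p = 0.00118). RSRC1, UBE2J1, FAM111B, ATAD5, MIR302B, MPDZ and SNX9 fell, with differences between -0.70 and -0.50. C3orf62 rose 1.58-fold (0.66 ± 0.14) and HYAL3, of the hyaluronidase family, rose 1.41-fold (0.50 ± 0.10). LPP, ZBTB20 (0.41 ± 0.10), PLEKHB1, ORC2, ZBTB44, MIDEAS, ASXL2 and H2BC12 rose by 0.32 to 0.41. In LPP, ZBTB20, MIDEAS, CCDC18, RSRC1 and UBE2J1 at least 1 further probe set had the opposite sign. Of 48 cell cycle genes 2 fell (3 when adjusted over the list alone), MCM7 (-0.26 ± 0.06) and MCM4 (-0.35 ± 0.09). TOP2A (-0.33 ± 0.10) and KIF2C (-0.29 ± 0.09) did not pass. The list median was -0.11 (camera adjusted p = 4.82e-11, and adjusted p = 0.981 with an estimated correlation). It was -0.051 without control replicate 1 (adjusted p = 0.000916) and -0.047 without VX replicate 3 (adjusted p = 0.000804). ACHE (-0.15 ± 0.16), BCHE (0.18 ± 0.07, adjusted p = 0.267), the 10 genes of acetylcholine synthesis and breakdown and the 12 receptor genes did not pass, nor did any when adjusted over the list alone. For these VX arrays the ACTB 3' minus 5' value was 0.28 higher than in the controls.

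Of the probe sets tested 348 of 279 genes passed, 33 higher and 315 lower, and 583 passed with the replicate block, which pairs the samples here. After adding the ACTB covariate 394 passed, 319 of them in both fits with 1 direction, among them 18 of the 20 genes. The count was 707 from the 2 groups alone, 1560 with array weights, 532 with the GAPDH covariate and 721 without the arrays numbered 1. It was 151, 208, 144 and 159 without control replicates 1, 2, 3 and 4, and 94, 230, 123 and 218 without VX replicates 1, 2, 3 and 4.

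After 0.1 µM VX at 72 h, TFAM, which packs and transcribes mitochondrial DNA, was 1.45-fold lower (-0.54 ± 0.10, adjusted p = 0.0108). DDX23, an RNA helicase of splicing, was 1.42-fold lower (-0.50 ± 0.09, adjusted p = 0.0114) and HES4, of the family of Notch-regulated repressors, was 1.39-fold lower (-0.47 ± 0.09). TPM4, a tropomyosin, was 1.94-fold lower (-0.95 ± 0.21). THRAP3, CHD4, CEP57, ALKBH2, SMOC1 and ZNF830 fell, with differences between -0.73 and -0.48. Without VX replicate 1 TPM4 (-0.67, adjusted p = 0.218), THRAP3 (-0.39, adjusted p = 0.113), CHD4 (-0.35, adjusted p = 0.265) and ZNF830 (-0.31, adjusted p = 0.244) did not pass. Nor did TPM4 without control replicate 1, 2, 3 or 4 (adjusted p = 0.0625, 0.102, 0.100 and 0.0650), from the groups alone (adjusted p = 0.255) or without the arrays numbered 1 (-0.66, adjusted p = 0.0710). The 8 genes that rose by the rule for named genes were SEC14L1P1 (0.65 ± 0.16), FOXP1, a forkhead transcription factor (0.28 ± 0.05, adjusted p = 0.0129), and GDAP2, ESS2, ZNF280B, SFR1, PAPOLG and RAP2B, at 0.27 to 0.45. TFAM, CEP57, SMOC1, ZNF830, GDAP2, ZNF280B, SFR1 and PAPOLG had at least 1 probe set of the opposite sign. Of 48 cell cycle genes 4 fell (9 when adjusted over the list alone): KIF2C (-0.42 ± 0.09), MCM2 (-0.31 ± 0.08), MCM3 (-0.30 ± 0.07) and MCM7 (-0.28 ± 0.06). The list median was -0.044 (camera adjusted p = 0.00110, and adjusted p = 0.973 with an estimated correlation). It was not called without VX replicate 2 (-0.024, adjusted p = 0.0684), and was at -0.089 without VX replicate 1 (adjusted p = 3.08e-05). The TGF-beta and BMP list was higher (median 0.10, camera adjusted p = 0.0176, and adjusted p = 0.973 with an estimated correlation), with 0 of 32 genes passing, also when adjusted over the list alone. SKIL was at 0.23 ± 0.08, INHBA at 0.33 ± 0.13, ACVR2A at 0.24 ± 0.10 and SMAD1 at 0.18 ± 0.08. SKIL, SMAD1 and ACHE had another probe set of the opposite sign. The TGF-beta and BMP list was not called without control replicate 1 (0.076, adjusted p = 0.294) or VX replicate 3 (0.068, adjusted p = 0.202). ACHE (-0.11 ± 0.16), BCHE (0.14 ± 0.07), the 10 genes of acetylcholine synthesis and breakdown and the 12 receptor genes did not pass. The VX arrays' ACTB 3' minus 5' value differed from that of controls by 0.049.

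At 72 h after 0.1 µM 178 probe sets of 138 genes passed, 32 higher and 146 lower, and all 178 also passed in the same direction with the ACTB covariate, where 505 did. The count was 0 from the 2 groups alone, where limma gave none, and 584 with array weights. It was 271 with a robust trended prior, 79 without the filter, 333 with a stricter one, 508 with the GAPDH covariate and 86 without the arrays numbered 1. Omitting single arrays gave 5 and 533 without VX replicates 1 and 3, and 118, 37, 36 and 44 without control replicates 1, 2, 3 and 4.

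**Figure D4:**
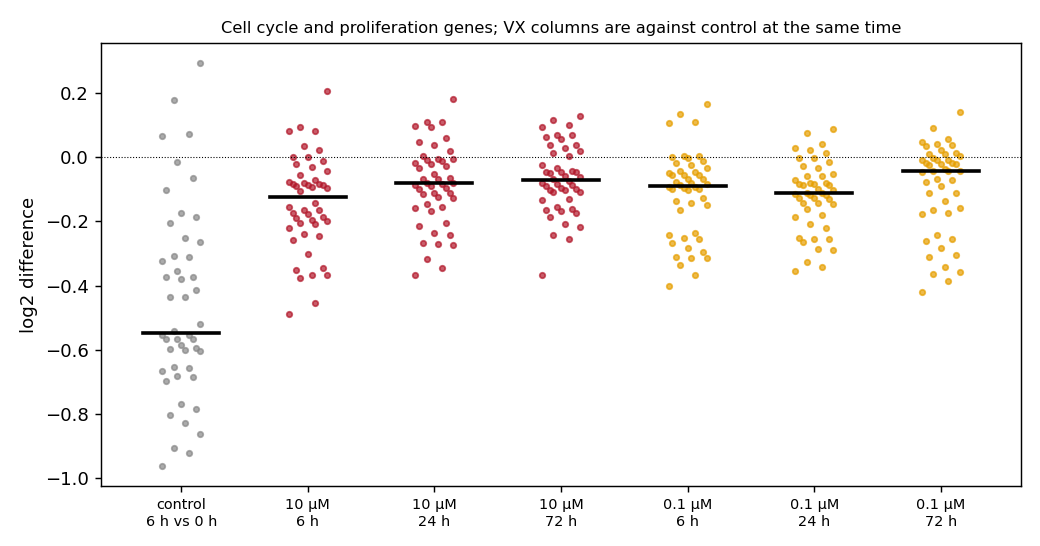
Log2 differences of the 48 cell cycle and proliferation genes between unexposed cells at 6 h and 0 h (grey) and between VX and unexposed cells at the same time (red 10 µM, orange 0.1 µM). Points are genes and bars are medians, -0.55 in the first column and between -0.12 and -0.044 in the VX columns.

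Between 10 µM and 0.1 µM VX, 0 of the 18 neuron markers passed at 6, 24 or 72 h (1, 1 and 0 higher when adjusted over the list alone), with medians of 0.023, 0.053 and 0.013. The 10 genes of acetylcholine synthesis and breakdown (medians -0.056, 0.024 and 0.044) and the 12 acetylcholine receptor genes (medians -0.0094, -0.15 and 0.099) had 0 passing at each time, also when adjusted over the list alone. For the 10 genes at 72 h camera's direction was down while the median and mean were above 0. The ACTB 3' minus 5' value was higher after 10 µM than after 0.1 µM by 0.866 at 6 h and 0.896 at 24 h (exact permutation p = 0.0286 for each, n = 4 against 4), and by 0.638 at 72 h (exact p = 0.229). Within the pairs at 6 h it was higher in 4 of 4 (exact permutation of signs, p = 0.125, the smallest 4 pairs allow). The 18S probe set differed by -1.10, -1.42 and -1.07 (exact permutation p = 0.0286, 0.0286 and 0.0857). In limma's test 42 probe sets of 30 genes differed at 6 h, 27 higher and 15 lower after 10 µM (28 and 29 with centred arrays). At 24 h 1 probe set without a single gene name was lower, and 330 of 252 genes differed at 72 h, 59 higher and 271 lower. At 6 h the replicate block, which pairs the samples here, gave 147. Array weights gave 2853, 1379 and 1190, and the groups alone 1, 0 and 20. At 6 h the count was 16 and 13 without 0.1 µM replicates 1 and 4, and 23, 11, 14 and 108 without 10 µM replicates 1, 2, 3 and 4. At 24 h, where 4156 probe sets had an unadjusted p under 0.05, it was 0, 2, 0 and 2 without 0.1 µM replicates 1, 2, 3 and 4 and 3, 0 and 0 without 10 µM replicates 1, 3 and 4. At 72 h it was 715, 211 and 210 without 0.1 µM replicates 1, 2 and 4 and 167 without 10 µM replicate 1.

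The probe sets that passed after both concentrations numbered 733 at 6 h, 111 higher and 622 lower, 266 at 24 h (28 and 238) and 39 at 72 h (13 and 26), all with 1 direction, and 1 more passed at 72 h with opposite directions. Independent lists of these sizes would share 7.95 higher and 69.02 lower at 6 h, 0.989 and 13.6 at 24 h, and 0.0829 and 2.38 at 72 h. Unchanged groups simulated against the same controls shared 2.23 on average and 223 at most at 6 h, and 0 at 24 h and 72 h, in 100 simulations. With the 4 controls split between the concentrations, in 6 ways, 18 to 42 probe sets passed in both at 24 h and 0 at 72 h. Across probe sets, which are not independent replicates, the differences correlated at 0.797, 0.738 and 0.610 (simulated 0.554, 0.518 and 0.483), with covariances of 0.0512, 0.0336 and 0.0230 (simulated 0.00853, 0.00787 and 0.00701). With the controls split the mean correlation was 0.485 at 24 h and 0.342 at 72 h, and the mean covariance 0.0259 and 0.0151. At 6 h the 3 controls were too few to split, so part of the excess may come from them. RNA quality may add to it: the ACTB value there was 2.16 and 1.29 higher after 10 and 0.1 µM. The simulations left out what same-numbered arrays share, which may add too. Deviations of these correlated between the concentrations at 0.509, 0.271 and 0.218 on average at 6, 24 and 72 h.

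Whether the effect of VX depended on time was tested as a difference between the 6, 24 and 72 h effects. After 0.1 µM, TCF7L2, a transcription factor of the WNT pathway, was named after its values were seen as the 1 probe set that passed (adjusted p = 0.00597): it was at -0.68 ± 0.13 at 6 h, -0.78 ± 0.12 at 24 h and 0.37 ± 0.12 at 72 h. Of its 6 other probe sets 0 passed after 0.1 µM at any time, and the brightest TCF7L2 probe set was at 0.08, 0.14 and 0.15. After 10 µM limma called 0 probe sets, 2663 had an unadjusted p under 0.05, the smallest adjusted p was 0.0558, and 2096 passed with array weights. That count of 0 became 5 and 50 without control 6 h replicates 1 and 3, and 1 without control 24 h replicate 2. It became 8 without 10 µM 6 h replicate 4, 3 and 4 without 10 µM 24 h replicates 2 and 4, and 1 without 10 µM 72 h replicate 4. After 0.1 µM it was 2 and 10 without control 6 h replicates 1 and 3, 2 without control 24 h replicate 2 and 6 without 0.1 µM 72 h replicate 1. Effects that passed at 1 time and not at another were otherwise not shown to differ.

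Unexposed cells at 6 h were compared with those at 0 h to give the course of the culture without VX. FOS and EGR1, immediate early transcription factors, rose 6.42-fold (2.68 ± 0.79, adjusted p = 0.0114) and 5.52-fold (2.46 ± 0.55, adjusted p = 0.00129). EGR3 rose 2.89-fold (1.53 ± 0.31). ETV5, TMTC1 (1.79 ± 0.15, adjusted p = 1.75e-10), CAV1, KCNJ2 and ALMS1-IT1 rose by 1.63 to 1.84. CEP128, a centriole protein, was 2.98-fold lower (-1.57 ± 0.12, adjusted p = 2.96e-11), and CCN2, a matrix-associated growth regulator, was 2.48-fold lower (-1.31 ± 0.23). BRINP3, FARS2, CCDC81, RAB3C, CENPI and PALMD fell, with differences between -1.36 and -1.25. Without 6 h replicate 1 ETV5 was at 1.22 (adjusted p = 0.00115), and CAV1 (0.85, adjusted p = 0.258) and KCNJ2 (0.91, adjusted p = 0.0734) did not pass. The cell cycle list was lower: 39 of 48 genes fell and 0 rose (40 when adjusted over the list alone). Among them were NDC80 (-0.91 ± 0.10), BUB1 (-0.96 ± 0.11), KIF20A (-0.78 ± 0.09) and CCNB2 (-0.69 ± 0.07), all of mitosis. Its median was -0.55 (camera adjusted p = 5.14e-18, adjusted p = 0.378 with an estimated correlation).

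In the same comparison 12 of 28 genes of the p53 and DNA damage list rose and 0 fell, also when adjusted over the list alone. They included MDM2 (0.80 ± 0.11), TNFRSF10B (0.61 ± 0.07), POLH (0.56 ± 0.09) and SESN1 (0.44 ± 0.07; camera adjusted p = 6.68e-06, adjusted p = 0.378 with an estimated correlation). Of 23 genes of the ATF4 and amino acid response 9 rose and 1 fell (9 and 2 when adjusted over the list alone). Those that rose included SESN2 (0.66 ± 0.08), CEBPB (0.78 ± 0.12), TRIB3 (0.64 ± 0.10) and the amino acid transporter SLC7A5 (0.63 ± 0.11; camera adjusted p = 0.000221, adjusted p = 0.378 with an estimated correlation). Of 23 genes of the unfolded protein response 5 rose, also when adjusted over the list alone. These included ATF4 (0.29 ± 0.07), DDIT3 (0.40 ± 0.10), HERPUD1 (0.35 ± 0.10) and XBP1 (0.38 ± 0.11; camera adjusted p = 0.0414, adjusted p = 0.945 with an estimated correlation). Of 33 immediate early genes 9 rose and 2 fell (9 and 3 when adjusted over the list alone). Among them were JUNB (0.94 ± 0.16), FOSB (1.45 ± 0.28) and, lower, CCN2 (camera adjusted p = 0.0127, adjusted p = 0.945 with an estimated correlation). CCNB2 and POLH had a further probe set of the opposite sign. Without 6 h replicate 1 the immediate early list was not called (median -0.041, adjusted p = 0.193), and without 6 h replicate 2 its median was 0.12 (adjusted p = 0.0123). The unfolded protein response list was not called without 0 h replicate 3 (0.062, adjusted p = 0.0515) or 4 (0.041, adjusted p = 0.0652). Nor was it called without 6 h replicate 1 (0.031, adjusted p = 0.142) or 3 (0.038, adjusted p = 0.112), and XBP1 did not pass without the latter (0.22, adjusted p = 0.209). Of the 14 progenitor and radial glia markers 1 rose and 2 fell, and of the 18 neuron markers 2 rose and 2 fell, with the same counts when adjusted over the list alone. At 6 h the ACTB 3' minus 5' value was 0.66 higher than at 0 h and the 18S probe set was at -0.96 against 0 h. In all, 9160 probe sets of 5102 genes passed, 4591 higher and 4569 lower (3942 and 5720 with centred arrays). Adding the ACTB covariate gave 8194, of which 7122 passed in both fits with 1 direction, and the count was 5808 without 6 h replicate 3. FOS was at 2.07 (adjusted p = 0.0991) without 6 h replicate 2.

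At 24 h without VX, FOLR1, a folate receptor, rose 2.80-fold over 0 h (1.49 ± 0.23, adjusted p = 0.000165). EGR1 rose 2.91-fold (1.54 ± 0.51, adjusted p = 0.0471), and CCZ1B, RASEF, RNA45SN5, CCDC152, NLN and LOC101927166 rose by 1.08 to 1.23. RGS5, a regulator of G protein signalling, was 2.61-fold lower (-1.39 ± 0.15, adjusted p = 7.27e-07). TAGLN, an actin-binding protein of contractile cells, was 2.34-fold lower (-1.23 ± 0.17). NPY2R, DOK5, ANXA1, RORA, LINC00472 and LRATD2 fell, with differences between -1.07 and -0.90. Of 14 progenitor and radial glia markers 1 rose and 2 fell, 1 of 18 neuron markers fell, and 0 of 39 lists differed from other genes in camera. NLN and TAGLN had probe sets of the opposite sign, of which 1 of NLN (-0.38, adjusted p = 0.00828) passed. The ACTB 3' minus 5' value was 1.52 higher than at 0 h. Of the probe sets 3911 of 2558 genes passed, 1454 higher and 2457 lower (1794 and 1747 with centred arrays). Including the ACTB covariate, 772 passed, 358 of them (9.15% of the 3911) in both fits with 1 direction. CCZ1B, NLN, LOC101927166, NPY2R, RORA and LINC00472 then did not pass. The count was 7734 with array weights, 1901 without 0 h replicate 1 and 2293 without 24 h replicate 3.

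At 72 h without VX, 7 of 34 genes of axon guidance and growth rose against 0 h and 0 fell (9 and 1 when adjusted over the list alone). They included EPHA5, an ephrin receptor (1.13 ± 0.27), STMN2, a microtubule regulator of growing axons (0.75 ± 0.14), DCC, a netrin receptor (0.70 ± 0.17), and NCAM1, a neural adhesion molecule (0.65 ± 0.19; camera adjusted p = 4.74e-06, adjusted p = 0.382 with an estimated correlation). The median of this list was 0.15, and 0.24 without 72 h replicate 1 (adjusted p = 2.2e-07). Of the 18 neuron markers 4 rose and 1 fell (9 and 4 when adjusted over the list alone). MAPT, which encodes tau, was at 0.50 ± 0.12, while TUBB3, a neuronal tubulin, fell (-0.44 ± 0.07, adjusted p = 0.000228; camera adjusted p for the list 0.00527, adjusted p = 0.382 with an estimated correlation). Of 21 cholesterol synthesis genes 7 fell, also when adjusted over the list alone. They included MVD (-0.74 ± 0.12), PMVK (-0.34 ± 0.07), IDI1 (-0.31 ± 0.06) and SQLE (-0.25 ± 0.06; camera adjusted p = 0.00583, adjusted p = 0.385 with an estimated correlation). Of 31 genes of oxidative phosphorylation 6 fell (7 when adjusted over the list alone). Among these were NDUFV1 (-0.30 ± 0.07), ATP5MC1 (-0.25 ± 0.06), ATP5PD (-0.23 ± 0.06) and NDUFB5 (-0.21 ± 0.06; camera adjusted p = 0.00527, adjusted p = 0.566 with an estimated correlation). Of 30 apoptosis genes 6 fell (8 when adjusted over the list alone). BIRC2, which inhibits death, was at -0.26 ± 0.08, CASP6 at -0.27 ± 0.08, BNIP3 at -0.21 ± 0.07 and DIABLO, which promotes death, at -0.19 ± 0.06 (camera adjusted p = 0.0233, adjusted p = 0.385 with an estimated correlation and 0.308 with the ACTB covariate).

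The largest single differences at 72 h were rises of EGR1 (1.65 ± 0.51), CCZ1B, SRGAP2, GRIA2, which encodes an AMPA receptor subunit (1.15 ± 0.26, adjusted p = 0.00431), ZNF345, EPHA5, LOC101927166 and NLN. The largest falls were those of DLK1, a Notch ligand of immature cells (-1.17 ± 0.30, adjusted p = 0.00972), GSAP, TMEM71, BTBD17, MAP1LC3C, GLIS3, RRAS and LYPD1, the last 7 between -1.09 and -0.85. NLN, NCAM1, IDI1, SQLE, NDUFV1 and ATP5PD had at least 1 probe set of the opposite sign. That of IDI1 (0.43, adjusted p = 0.0190) passed. The apoptosis list was not called without 72 h replicate 4 (-0.11, adjusted p = 0.0631). The ACTB 3' minus 5' value was 1.56 higher than at 0 h. In all, 4186 probe sets of 2701 genes passed, 1721 higher and 2465 lower. Under the ACTB covariate 1635 passed, 688 of them (16.4% of the 4186) in both fits with 1 direction. LOC101927166, NLN, TMEM71, BTBD17, GLIS3 and RRAS then did not pass. The count was 8476 with array weights, 2086 without 0 h replicate 1 and 2551 without 72 h replicate 1, and 2776 without 72 h replicate 4.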

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

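The tests of RNA quality, of the cell cycle list in unexposed cells and of histone genes were chosen after the results were seen, as was the naming of the 4 linker histone genes. The counts over other splits of the arrays were planned before the data were examined.

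Of 299 groups of arrays tested for 1 array far from the others, 23 held one, where chance, at about 1 in 20 groups, gives 14.95, and 15 of the 23 were arrays with the replicate number 1. Among replicates 1, the ACTB 3' minus 5' value was 3.26 in unexposed cells at 72 h against 2.02 to 2.08 in the others, and the GAPDH value was 0.913 in unexposed cells at 24 h against 0.650 to 0.692, 1.05 in unexposed cells at 72 h against 0.540 to 0.593, 1.88 after 10 µM VX at 24 h against 0.917 to 1.05, and 1.61 after 10 µM at 72 h against 0.728 to 0.840. ACTB in unexposed cells at 0 h was 1.12 in replicate 4 against 0.665 to 0.737. After 0.1 µM at 6 h, replicate 1 had LINC02239 at 6.19 against 5.68 to 5.76 and ZNF767P at 5.53 against 6.11 to 6.15. After 0.1 µM at 24 h, replicate 1 had ORC2 at 8.51 against 8.35 to 8.36 and UBE2J1 at 8.67 against 9.02 to 9.06. After 0.1 µM at 72 h, replicate 1 had RAP2B at 10.61 against 10.4 to 10.43, TPM4 at 7.31 against 8.38 to 8.55 and THRAP3 at 9.06 against 10.36 to 10.51. M6PR at 72 h was 7.95 in replicate 1 after 10 µM against 8.75 to 8.81, and 9.24 in replicate 1 of the unexposed cells against 9.46 to 9.48. RAB12 was 6.94 in replicate 1 of the unexposed cells at 24 h against 7.42 to 7.47. In unexposed cells at 72 h, H3-3A was 7.95 in replicate 2 against 7.67 to 7.71, H2AC17 was 7.29 in replicate 3 against 7.02 to 7.06, and GRIA2 was 7.55 in replicate 4 against 7.17 to 7.22. NLN was 9.13 in replicate 3 of the unexposed cells at 24 h against 9.30 to 9.31, and NPY2R was 5.45 in replicate 3 at 0 h against 5.25 to 5.27. BCHE was 10.08 in replicate 4 after 10 µM at 6 h against 10.37 to 10.41, and ACHE was 5.21 in replicate 4 after 10 µM at 24 h against 5.94 to 6.06.

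TCF7L2 was the 1 probe set whose effect of 0.1 µM VX differed between the times (adjusted p = 0.00597), at -0.68 at 6 h, -0.78 at 24 h and 0.37 at 72 h. The same probe set was at -0.60, -0.40 and -1.43 after 10 µM (adjusted p = 0.0558), and the brightest TCF7L2 probe set was at 0.08, 0.14 and 0.15 after 0.1 µM. Of 100 shuffles of the times, 11 called as many probe sets as the 1 after 0.1 µM and up to 2784, and 100 as many as the 0 after 10 µM and up to 5819. These shuffles do not decide whether chance can be excluded, because any shuffle reaches 0 and because 6496 probe sets differed between the times in unexposed cells, which shuffled times carry into the test.

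Among the 35 splits of the arrays of each comparison, the real one called the most probe sets for 10 µM at 24 h (2626 probe sets, 143 in the highest other split, 1 split as large with the real one) and 72 h (677 and 36, 1). It can also be excluded for unexposed cells at 6 h (9160 and 5127, 1), 24 h (3911 and 1, 1) and 72 h (4186 and 1, 1) against 0 h. Other splits called as many or more for 0.1 µM at 72 h (178 and 265, 2), and for 10 against 0.1 µM at 24 h (1 and 1, 2) and 72 h (330 and 448, 3). There the splits do not argue against chance. In the 4 comparisons whose replicate numbers pair the samples, the splits that part as many pairs number 8, too few for a share under 0.05. Their highest count beside the real one was 5035 against the real 3874 for 10 µM at 6 h, 41 against 1176 for 0.1 µM at 6 h, 0 against 348 for 0.1 µM at 24 h and 0 against 42 for 10 against 0.1 µM at 6 h. Over all splits of these comparisons 2, 1, 1 and 4 were as large, and the splits that part fewer pairs called up to 2113, 993, 2 and 1303. The splits with 993 and 1303 part 0 pairs, so they set replicate numbers against each other, and 1303 is many times the real 42, which points to a structure of the samples by replicate number. With the replicate block these 4 comparisons called 6003, 2597, 583 and 147. The cell cycle list was called as strongly in 15 and 2 splits for 10 µM at 24 and 72 h (smallest unadjusted camera p of the other splits 2.55e-23 and 1.54e-05 against the real 4.33e-06 and 0.000148) and in 4 for 0.1 µM at 72 h (3.22e-06 against 2.83e-05), so chance is not excluded there. For 10 µM at 6 h and 0.1 µM at 6 and 24 h, 10, 9 and 11 of all splits did so (6.28e-12, 1.93e-11 and 4.17e-32 against the real 4.73e-06, 0.000116 and 1.24e-12). Of the 8 that part as many pairs 2, 1 and 1 did, again too few (smallest other 2.31e-06, 0.000199 and 8.65e-09). At 6 h without VX only the real split did (p 1.32e-19), but another came near (1.09e-18), so chance stays open.

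Part of the differences called after VX went with the RNA quality of the arrays: among probe sets called after 10 µM at 6, 24 and 72 h, 86.2%, 79.5% and 84.2% had a slope on the ACTB value within groups of the same sign as their difference, and after 0.1 µM 73.0%, 86.8% and 81.5%, against 66.3%, 57.6%, 62.4%, 65.4%, 52.0% and 57.0% of all tested. With the ACTB covariate, 2.04%, 13.6% and 46.5% of the calls at 6, 24 and 72 h after 10 µM still passed in the same direction. After 0.1 µM, 19.3%, 91.7% and 100% did. This argues against 3' bias as the whole cause except at 10 µM and 6 h and at 0.1 µM and 72 h. In the last ACTB differed too little to test (0.049). The calls' median size went from 0.50 to 0.18 and 0.49 to 0.33 at 6 and 24 h after 10 µM. At 6 h after 0.1 µM it went from 0.46 to 0.34. Each moved by more than its median SE (0.132, 0.127 and 0.115). A 3' bias may explain most calls in the first and part in the others. The size moved within the SE at 10 µM and 72 h (0.56 to 0.48). So it did at 0.1 µM and 24 h (0.57 to 0.54) and 72 h (0.485 to 0.479), which leaves a part open. Labelling and RNA integrity cannot be told apart, since the spiked poly-A controls reached at most 3.52 on the log2 scale, under the filter value of 4.71. An effect of VX on RNA integrity stays open too: the ACTB value was 2.16 higher after 10 µM at 6 h, and the order in which the arrays were processed is not given in the sources used here.

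In unexposed cells the cell cycle list was lower at 6 h than at 0 h, with a median of -0.55. The median was -0.53 with the ACTB covariate, which argues against the bias that the ACTB value measures as its whole cause. The 18S probe set near the 5' end also moved with this fall, at -0.96 against 0 h (exact permutation p = 0.0286), and was not used as a covariate, so a difference in RNA quality that the ACTB value does not carry stays open. A loss of progenitor cells as a whole may contribute: the progenitor and radial glia markers had a median of -0.15, with an SD of 0.33 between members that leaves it open. No group of the design tests another biological explanation.

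Of the linker histone genes H1-2, H1-3, H1-4 and H1-5, 3 fell at 24 h and 3 at 72 h after 10 µM VX, with medians of -0.81 and -0.74, while H1-10, H1-6, H1-7 and H1-8 did not pass. These falls are against unexposed cells of the same time. For H1-3 the unexposed arrays lay at 6.84 to 7.30 at 0 h, 7.57 to 7.83 at 24 h and 7.68 to 8.17 at 72 h. After 10 µM its arrays lay at 6.62 to 6.97 at 24 h and 6.87 to 7.31 at 72 h, near those of 0 h. Leaving out 1 array gave 2 falls at 24 h in all but the fit without VX replicate 2 (medians -0.88 to -0.74), and at 72 h 1 without control replicate 2 or 3 or VX replicate 1, 3 without control replicate 1 and 2 in the others (medians -0.79 to -0.69), and at least 73.0% of the median was kept with the ACTB covariate, but 1 of the 4 genes passed at each time, so after 10 µM a 3' bias cannot be told apart from another cause. After 0.1 µM, where 0 passed, the medians were -0.56 at 24 h and -0.64 at 72 h, and -0.51 and -0.63 with the covariate, but at 72 h they were -0.28 and -0.30 without VX replicate 1, whose ACTB value of 3.09 was the highest of its group, so they do not decide about 3' bias. The 39 other genes with histone symbols include pseudogenes, an antisense RNA and some with means under the filter value. After 10 µM their medians were -0.012 at 24 h and -0.067 at 72 h (SD 0.26 and 0.23). The 4 lay lower by over that SD but were named from the results, so an equal fall of all stays open. Of the 39, 3 fell and 2 rose at 24 h, and 2 fell and 0 rose at 72 h. The effect of VX itself was not tested apart from RNA quality.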

How the results depend on the processing

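The ACTB and GAPDH covariates and the omission of the arrays numbered 1 were chosen after the data were seen. Over 276 pairs of a named gene and a comparison, 5436 values were computed under an alternative: 4213 kept direction and side of the threshold, 1066 kept direction but no longer passed, 53 newly passed and 104 changed sign. Dim signals, near the filter value, limit what small differences can show. Of the values that no longer passed, 526 came from leaving out 1 array, 145 from another probe set, 105 from the ACTB covariate, 104 from the compared groups alone, 52 from omitting the arrays numbered 1, 49 from the GAPDH covariate, 38 from no filter, 28 from centred arrays and 15 from no shrinkage. Some array, when left out, ended the call of 16 of 35 named genes that passed for 10 µM and 6 h, 20 of 28 for 10 µM and 24 h, 14 of 21 for 10 µM and 72 h, 22 of 22 for 0.1 µM and 6 h, 18 of 22 for 0.1 µM and 24 h, 22 of 22 for 0.1 µM and 72 h, 5 of 34 for 6 h without VX, 2 of 16 for 24 h without VX and 11 of 41 for 72 h without VX. Given here are counts and lists that moved and values that changed sign, and other values of single genes only where the comparisons name them. Unless stated, the cause was not tested.

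With only the arrays of the groups compared the count was 711 for 10 µM and 6 h, 351 for 10 µM and 72 h, 73 for 0.1 µM and 6 h, 707 for 0.1 µM and 24 h and 0 for 0.1 µM and 72 h. It was 1 for 10 against 0.1 µM at 6 h, 0 for 10 against 0.1 µM at 24 h, 20 for 10 against 0.1 µM at 72 h and 3 for times at 10 µM. With the replicate number as a block the count was 6003 for 10 µM and 6 h, 4023 for 10 µM and 24 h, 1281 for 10 µM and 72 h, 2597 for 0.1 µM and 6 h and 583 for 0.1 µM and 24 h. It was 482 for 0.1 µM and 72 h, 147 for 10 against 0.1 µM at 6 h, 91 for 10 against 0.1 µM at 24 h and 603 for 10 against 0.1 µM at 72 h. With array weights the count was 10693 for 10 µM and 6 h, 6377 for 10 µM and 24 h, 2339 for 10 µM and 72 h, 4232 for 0.1 µM and 6 h and 1560 for 0.1 µM and 24 h. It was 584 for 0.1 µM and 72 h, 2853 for 10 against 0.1 µM at 6 h, 1379 for 10 against 0.1 µM at 24 h, 1190 for 10 against 0.1 µM at 72 h and 7734 for 24 h without VX. It was 8476 for 72 h without VX, 2096 for times at 10 µM and 71 for times at 0.1 µM. With the ACTB covariate the count was 246 for 10 µM and 6 h, 629 for 10 µM and 24 h, 352 for 10 µM and 72 h, 435 for 0.1 µM and 6 h and 505 for 0.1 µM and 72 h. It was 7 for 10 against 0.1 µM at 24 h, 772 for 24 h without VX and 1635 for 72 h without VX. With the GAPDH covariate the count was 1410 for 10 µM and 6 h, 532 for 0.1 µM and 24 h, 508 for 0.1 µM and 72 h, 107 for 10 against 0.1 µM at 6 h and 23 for 10 against 0.1 µM at 24 h. It was 604 for 10 against 0.1 µM at 72 h and 13 for times at 10 µM. Without the arrays numbered 1 the count was 1283 for 10 µM and 72 h, 1802 for 0.1 µM and 6 h, 721 for 0.1 µM and 24 h, 86 for 0.1 µM and 72 h and 92 for 10 against 0.1 µM at 6 h. It was 46 for 10 against 0.1 µM at 24 h, 695 for 10 against 0.1 µM at 72 h, 3 for times at 10 µM and 7 for times at 0.1 µM. Without the filter the count was 79 for 0.1 µM and 72 h and 0 for 10 against 0.1 µM at 24 h. With the stricter filter the count was 333 for 0.1 µM and 72 h, 6 for 10 against 0.1 µM at 24 h, 4 for times at 10 µM and 2 for times at 0.1 µM. With a robust trended prior the count was 271 for 0.1 µM and 72 h, 5 for 10 against 0.1 µM at 24 h, 4 for times at 10 µM and 2 for times at 0.1 µM. Without shrinkage the count was 7 for 10 against 0.1 µM at 24 h and 2 for times at 0.1 µM. With centred arrays the count was 0 for 10 against 0.1 µM at 24 h. At an adjusted p of 0.1 the count was 1636 for the overlap at 6 h, 436 for the overlap at 24 h and 136 for the overlap at 72 h. With split controls the count was 28.7 for the overlap at 24 h and 0 for the overlap at 72 h. The rule by which replicate numbers were taken to pair the samples was met only in the 4 comparisons named with the pairing check. The block changed no other call of a list or named gene than those given here and in the comparisons. The block gave new calls for CDC45, BAX, AURKB, HES4, SYT4 and ATP2B1 and ended none of a named gene. FOS, outside the rule for named genes there, also passed with it for 0.1 µM and 6 h (-1.64, adjusted p = 0.0160) and 10 µM and 24 h (-2.04, adjusted p = 0.00100). In no comparison outside those 4 did every array correlate best with its own number, and the lowest correlation of same-numbered arrays there lay between -0.17 and 0.077.

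Leaving out each array in turn gave the following lowest and highest values. Counts ran from 1918 to 5698 for 10 µM and 6 h, 1125 to 2748 for 10 µM and 24 h, 290 to 1087 for 10 µM and 72 h, 12 to 2003 for 0.1 µM and 6 h and 94 to 230 for 0.1 µM and 24 h. Counts ran from 5 to 533 for 0.1 µM and 72 h, 11 to 108 for 10 against 0.1 µM at 6 h, 0 to 3 for 10 against 0.1 µM at 24 h, 167 to 715 for 10 against 0.1 µM at 72 h and 5808 to 9494 for 6 h without VX. Counts ran from 1901 to 3645 for 24 h without VX, 2086 to 3856 for 72 h without VX, 0 to 50 for times at 10 µM and 1 to 10 for times at 0.1 µM. Differences for the cell cycle list at 10 µM ran from -0.18 to -0.064 at 6 h and -0.12 to -0.032 at 24 h. At 72 h they ran from -0.085 to -0.053, and from -0.094 to -0.042 for p53 and DNA damage response. For the cell cycle list at 0.1 µM they ran from -0.14 to -0.05 at 6 h and -0.16 to -0.047 at 24 h. At 72 h they ran from -0.089 to -0.024, and from 0.068 to 0.12 for TGF-beta and BMP signalling. Differences ran from -0.041 to 0.24 for immediate early genes at 6 h without VX, 0.031 to 0.083 for unfolded protein response at 6 h without VX, 0.022 to 0.078 for calcium signalling at 72 h without VX and 0.008 to 0.056 for synaptic vesicle and synapse at 72 h without VX. Differences ran from -0.15 to -0.11 for p53 and DNA damage response at 72 h without VX, -0.17 to -0.11 for apoptosis at 72 h without VX, 0.027 to 0.066 for Notch signalling at 72 h without VX and 0.13 to 0.24 for axon guidance and growth at 72 h without VX.

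No list called by camera kept its call with an estimated correlation, which leaves the medians as they are. For the cell cycle list they were -0.12, -0.082 and -0.072 at 6, 24 and 72 h after 10 µM. After 0.1 µM they were -0.09, -0.11 and -0.044. They were -0.06 for p53 at 10 µM and 72 h and 0.10 for TGF-beta and BMP at 0.1 µM and 72 h. They were 0.18 for immediate early genes at 6 h without VX, 0.075 for unfolded protein response at 6 h without VX, 0.19 for ATF4 and amino acid response at 6 h without VX and 0.23 for p53 and DNA damage response at 6 h without VX. They were -0.55 for cell cycle and proliferation at 6 h without VX, 0.036 for calcium signalling at 72 h without VX, 0.051 for synaptic vesicle and synapse at 72 h without VX and -0.14 for p53 and DNA damage response at 72 h without VX. They were -0.15 for apoptosis at 72 h without VX, -0.12 for cholesterol synthesis at 72 h without VX, -0.086 for oxidative phosphorylation at 72 h without VX and 0.031 for Notch signalling at 72 h without VX. They were 0.15 for axon guidance and growth at 72 h without VX and 0.19 for markers of neurons at 72 h without VX. In fry the calls that ended had the medians -0.12, -0.082, -0.06, -0.072, -0.09, -0.11, -0.044, 0.10, 0.18, 0.075, 0.036, 0.051, 0.031 and 0.19. Omitting the arrays numbered 1 ended the calls of cell cycle and proliferation at 10 µM and 24 h (-0.056, adjusted p = 0.0992), cell cycle and proliferation at 10 µM and 72 h (-0.058, adjusted p = 0.062), TGF-beta and BMP signalling at 0.1 µM and 72 h (0.044, adjusted p = 0.174), immediate early genes at 6 h without VX (-0.015, adjusted p = 0.22) and unfolded protein response at 6 h without VX (0.043, adjusted p = 0.119). Without the filter calcium signalling at 72 h without VX was at 0.018 (adjusted p = 0.119). With the ACTB covariate apoptosis at 72 h without VX was at -0.08 (adjusted p = 0.308). The 3' minus 5' difference of GAPDH in place of ACTB at 10 µM and 6 h was 0.786 (exact p = 0.0571).

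The probe sets of 1 gene read different parts of its transcripts, and the following other probe sets had the opposite sign. For 10 µM and 6 h they were those of THBS1 (-0.17 and -0.27), IDNK (-0.091), XKR6 (-0.33 and -0.16), PGD (0.039), ANP32A (0.083), AURKB (0.28), TOP2A (0.41), CASP6 (0.34) and PKM (0.61). For 10 µM and 24 h they were those of TBRG1 (-0.61, -0.30 and -0.12), SDCBP2-AS1 (-0.18), RAB12 (-0.71), KIF1A (0.16), MKI67 (0.19), CPLX2 (-0.12) and VAMP1 (-0.19). For 10 µM and 72 h they were those of IDNK (-0.047), ZBTB20 (-0.087 and -0.14), ARHGAP32 (-0.13), KAT6A (-0.51 and -0.19), FOXP1 (-0.70 and -0.056), ZNF830 (0.012), MKI67 (0.095 and 0.09) and ZMAT3 (0.15, 0.035 and 0.056). For 0.1 µM and 6 h they were those of THBS1 (-0.065), ARHGAP30 (-0.30) and ACHE (-0.022). For 0.1 µM and 24 h they were those of LPP (-0.37, -0.006 and -0.27), ZBTB20 (-0.14), MIDEAS (-0.088), CCDC18 (0.079 and 0.032), RSRC1 (0.076 and 0.007) and UBE2J1 (0.008, 0.12 and 0.14). For 0.1 µM and 72 h they were those of GDAP2 (-0.035), ZNF280B (-0.19 and -0.037), SFR1 (-0.042), PAPOLG (-0.15), TFAM (0.075 and 0.21), CEP57 (0.001, 0.11, 0.091 and 0.051), SMOC1 (0.055), ZNF830 (0.006), ACHE (0.03), SKIL (-0.20) and SMAD1 (-0.019). For 24 h without VX they were those of NLN (-0.11, -0.25 and -0.38) and TAGLN (0.089). For 72 h without VX they were those of NLN (-0.22, -0.22 and -0.007), NCAM1 (-0.21), IDI1 (0.43 and 0.17), SQLE (0.20 and 0.18), NDUFV1 (0.20), ATP5PD (0.12), DLL3 (-0.49), SPATA18 (0.017), CACNA1B (-0.088), PPP3CB (-0.044) and CAMK1 (-0.002). For 6 h without VX they were those of CCNB2 (0.09) and POLH (-0.17). With the ACTB covariate the sign changed for RPL23AP32 at 10 µM and 6 h (-0.13), EIF5A at 10 µM and 6 h (0.40), PSMC3 at 10 µM and 6 h (0.034), PPIE at 10 µM and 6 h (0.039), BCHE at 10 µM and 6 h (-0.04), ACHE at 0.1 µM and 6 h (-0.011) and AIFM1 at 10 µM and 6 h (0.067). With the replicate number as a block the sign changed for ACHE at 10 µM and 6 h (0.014). Without the arrays numbered 1 the sign changed for ACHE at 10 µM and 6 h (0.067) and ACHE at 10 µM and 72 h (0.028). ACHE, which never passed, changed sign when 1 array was left out, to 0.072, 0.022, 0.079, 0.045, 0.038, -0.046, -0.024 and 0.046. Its ranges were -0.13 to 0.072 for 10 µM and 6 h, -0.20 to 0.079 for 10 µM and 24 h, -0.072 to 0.045 for 10 µM and 72 h, -0.046 to 0.16 for 0.1 µM and 6 h and -0.20 to 0.046 for 0.1 µM and 72 h.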

Other observations

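Camera called 4 further gene lists, described here after their results were seen, in unexposed cells at 72 h against 0 h. Of 22 Notch signalling genes 1 rose, also when adjusted over the list alone, HES1, a target of the pathway (0.55 ± 0.13, adjusted p = 0.00556, n = 4 against 4). HES4 was at 0.26 ± 0.09, DLL3 at 0.30 ± 0.11 and NUMB, an inhibitor of Notch, at 0.52 ± 0.21 (list median 0.031, camera adjusted p = 0.00583, adjusted p = 0.385 with an estimated correlation). The Notch median was 0.066 and 0.050 without 0 h replicates 2 and 4, and 0.048, 0.053 and 0.065 without 72 h replicates 1, 2 and 3, with adjusted p of at most 0.0444 over the arrays left out. Of 30 synapse genes 2 rose (1 when adjusted over the list alone), NRXN2 (0.65 ± 0.14) and NRXN3 (0.44 ± 0.15), adhesion proteins of the presynaptic side (list median 0.051, camera adjusted p = 0.0169, adjusted p = 0.443 with an estimated correlation). This list was not called without 72 h replicate 4 (median 0.028, adjusted p = 0.0631), and its median was 0.014 and 0.028 without 0 h replicates 2 and 4 (adjusted p = 0.0186 and 0.0249) and 0.008 without 72 h replicate 1 (adjusted p = 0.00654). Of 25 calcium signalling genes 1 rose, also when adjusted over the list alone, CACNA1B, which encodes a presynaptic calcium channel (0.67 ± 0.14, adjusted p = 0.00230; list median 0.036, camera adjusted p = 0.0466, adjusted p = 0.382 with an estimated correlation). The calcium list was not called without 0 h replicate 3 (0.022, adjusted p = 0.0971) or 72 h replicate 3 (0.040, adjusted p = 0.101) or 4 (0.027, adjusted p = 0.124). Its median was 0.078 and 0.058 without 0 h replicates 1 and 2 (adjusted p = 0.0378 and 0.0425).

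Of 28 genes of the p53 and DNA damage list, 12 of which rose at 6 h, 4 fell at 72 h against 0 h without VX (10 when adjusted over the list alone): GADD45B (-0.47 ± 0.11), GADD45A (-0.39 ± 0.09), SPATA18 (-0.45 ± 0.15) and FAS, a death receptor (-0.40 ± 0.14). The list median was -0.14 (camera adjusted p = 0.0233, adjusted p = 0.566 with an estimated correlation), and it was not called without 72 h replicate 3 (-0.11, adjusted p = 0.111). Of 10 fibroblast and mesenchyme markers 2 fell at 6 h, 3 at 24 h and 1 at 72 h (4, 3 and 2 when adjusted over the list alone), with COL3A1, a collagen gene named after its values were seen, at -0.41 ± 0.09, -0.68 ± 0.08 and -0.56 ± 0.08. In fry the adjusted p of these markers was 0.0303, 0.00186 and 0.0191, and in camera, against other genes, 0.605, 0.192 and 0.295. The ACTB 3' minus 5' value was 1.56 higher at 72 h than at 0 h. CACNA1B and SPATA18 had another probe set of the opposite sign, as did DLL3, whose other probe set fell (-0.49, adjusted p = 0.0117).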
